A study of Mus musculus with 6 samples.

How the data were processed

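Gene-level RNA was measured in 6 heart libraries from mice with myocardial infarction. Per the labels each is from the whole heart, but in 5 of the 6 the atrial transcripts Myl7 and Sln held at most 18 and 6 counts, against 28312 and 9832 in room temperature 1, which goes against a whole heart with its atria for those 5. Per the labels, 3 libraries came from mice kept in mild cold (16 °C for 7 days) and 3 from mice kept at room temperature (22 °C). Total RNA was taken with TRIzol and enriched for mRNA before sequencing, per the labels' protocols. The deposited values are raw counts per gene, whole numbers that had not been normalized. The submitters' processing notes name featureCounts 2.0.3 and the mouse build GRCm39. The aligner, the annotation release, the strand setting and the handling of read pairs are not given in the sources used here. Between 71.9% and 78.3% of the counts from 1 to 10 in a library were even. That pattern is left when both mates of a pair are counted as separate reads, so the number of sequenced fragments can be lower than the count.

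The table held 55401 versioned Ensembl gene IDs. Symbols came from the GENCODE M21 annotation, matched on the ID without its version. A symbol was found for 55141 IDs, and 54349 of the IDs had the same version in M21. The 260 IDs without a symbol held at most 0.0021% of a library's counts. M21 is built on an earlier assembly than GRCm39, so it was used only for names, gene length, GC content and overlap between genes, and no coordinates are given. Total counts per library were 65285901, 43163355 and 42139438 in mild cold 1 to 3, and 41619023, 41920592 and 63946671 in room temperature 1 to 3.

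Genes were tested with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood test (2-sided, without robust estimation), after its default expression filter by group and scaling by the trimmed mean of M-values (TMM). The design held the group only. The filter kept 16757 genes, and p-values were adjusted by the Benjamini-Hochberg method over those genes, with 0.05 as the threshold. Levels are TMM-scaled CPM, the count of a gene relative to the scaled library total, given as mean ± SD over 3 libraries, and log2 fold changes are mild cold over room temperature with the standard error (SE) from the test. TMM factors were 0.943, 0.865 and 0.942 in mild cold 1 to 3 and 1.136, 0.996 and 1.151 in room temperature 1 to 3. Counts of every pair of libraries were compared, and no pair held the same values.

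Before the data were examined, 41 gene lists were fixed, 25 of them on biology and 16 on cell types, with 957 different symbols, of which 881 were tested. The 40 lists with at least 3 tested members were tested with camera from limma 3.58.1 (preset inter-gene correlation 0.01, adjusted over the 40 lists). Members of a list were also adjusted over the list alone with edgeR's p-values. A named gene is said to have risen or fallen where it passed in that way. Smad2, Ahr and the summed matrix list were also compared on log2(CPM + 1) by an exact 2-sided permutation test, which has 10 splits and cannot give a p below 0.1. The labels number the replicates but do not say whether they came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

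The genes named were chosen by a rule fixed before the data were examined. It took 26 study genes whatever their result, the 10 genes with the largest change in each direction among those past the threshold (or, where none passed, the 5 with the smallest p and a mean of at least 2 CPM in each direction, without overlap between the groups), and up to 4 members of each list by smallest p. Some genes that the rule takes are not reported here. Tissue marker genes outside that rule were chosen after their values were seen. On simulated counts for 16392 genes in 3 against 3 libraries, the same test recovered 9 of 50 genes changed 1.5-fold, 30 of 50 changed 2-fold, 46 of 50 changed 4-fold and 49 of 50 changed 8-fold, with 16 false calls. A list shifted in the simulation was called at adjusted p = 5.76e-17, and 0 of 39 unshifted lists were called. Genes were drawn independently there, while the real matrix and nuclear oxidative phosphorylation lists had estimated inter-gene correlations of 0.749 and 0.639. The simulation therefore cannot show how often camera calls unshifted lists of correlated genes. Its recovery of single genes need not hold for the real data either. Each gene was drawn at its fitted dispersion, and an adjusted p depends on how many other genes changed.

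Alternatives of scaling fixed beforehand were DESeq2 size factors, library totals only, upper-quartile scaling, and TMM scaling after leaving out mitochondrially encoded and haemoglobin genes. Filters and tests fixed beforehand were no expression filter, at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom and robust estimation. Also fixed beforehand were thresholds of 0.01 and 0.1, the replicate number as a block, an estimated inter-gene correlation and fry. Pseudocounts of 0.1 and 5 and leaving out each library were fixed beforehand too. Alternatives chosen after seeing the data were counts halved to approximate fragments, leaving out the 2 deepest libraries, leaving out members of the atrial, adipocyte and skeletal muscle lists, and removing a trend on gene length and GC content.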

Results

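The data were RNA-seq counts from hearts of mice after myocardial infarction, the loss of heart muscle that follows a blocked coronary artery. The labels call each sample a whole heart, but atrial transcripts were nearly absent from 5 of the 6 libraries (Myl7 at most 18 counts, against 28312 in room temperature 1), which goes against that label for those 5. Hearts of mice kept in mild cold (3 libraries) were compared with hearts of mice kept at room temperature (3 libraries), and the room temperature libraries gave the background for every value. Library totals ran from 41619023 to 65285901 counts. The deepest library of each group was mild cold 1 (65285901 counts) and room temperature 3 (63946671 counts). Mitochondrially encoded genes took 36.6 ± 3.81% of the counts in mild cold and 28.4 ± 2.86% at room temperature, a difference of 8.27 percentage points (SD, n = 3 per group, exact permutation p = 0.1, the smallest this design allows).

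The comparison asked how 7 days of mild cold change gene expression in the infarcted heart, with SMAD2, a transducer of TGF-beta signals, and AHR, the aryl hydrocarbon receptor, named in the title of the series. In mild cold, nuclear genes of mitochondrial respiration were higher, with a median of 1.42-fold over 74 genes (camera adjusted p = 3.73e-48 with the preset correlation, but adjusted p = 0.375 with an estimated correlation). Extracellular matrix genes were lower, with a median fold of 0.577 over 40 genes (4e-20, but adjusted p = 0.411 with an estimated correlation). TGF-beta target genes were lower too, with a median fold of 0.656 over 26 genes (2.36e-11, but adjusted p = 0.0736 with an estimated correlation). Of 40 lists, 27 passed with the preset correlation and 0 with an estimated correlation. Among single genes, Tgfb2, a TGF-beta ligand, was at 16.5 ± 1.19 CPM in mild cold and 34.5 ± 3.22 CPM at room temperature, and Cox7a1, the heart and muscle form of a cytochrome c oxidase subunit, was at 404.5 ± 47.2 and 197 ± 19.7 CPM (SD, n = 3 per group). None of the 16757 genes passed edgeR's adjusted p of 0.05, where the smallest adjusted p was 0.0813. At an unadjusted p under 0.05 there were 3295 genes (1526 higher and 1769 lower in mild cold), where 838 are expected on average by chance. For 4205 genes, 25.1%, the groups did not overlap, where 10% are expected on average by chance. Correlated genes can depart far from these averages together. The highest other split of the 6 libraries gave 1557 genes at an unadjusted p under 0.05, and with 10 splits chance cannot be excluded. The DESeq2 Wald test called 1252 genes at 0.05 (547 higher, 705 lower), and 393 of the 396 genes past edgeR's adjusted p of 0.1 were among them, all in the same direction. Scaling to library totals alone moved the median log2 fold change of all genes from -0.02 to -0.28 and called 356 genes, 10 higher and 346 lower. Limma-voom called 0.

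The genes with the smallest p in each direction did not pass over all genes (edgeR adjusted p = 0.0813 for each). Higher in mild cold were Klhl33 (36.1 ± 4.46 against 11.1 ± 2.82 CPM), Cox7a1, Acer2, an alkaline ceramidase (log2 fold change 0.78), Pla2g12a, a secreted phospholipase (0.69), and Mid1ip1, a regulator of fatty acid synthesis (0.85). Lower in mild cold were Hbegf, an EGF family ligand (17.0 ± 1.11 against 33.8 ± 1.48 CPM), Tgfb2, Cpxm1 (log2 fold change -1.32), Tiam1, an activator of Rac (-1.02), and Scin, an actin-severing protein (-1.29).

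Genes of mitochondrial energy metabolism moved upward together. Of 74 nuclear-encoded subunits of oxidative phosphorylation, 73 rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 3.73e-48, and adjusted p = 0.375 with an estimated correlation). Cox7a1 rose 2.05-fold, Ndufs7 1.56-fold and Cox5a 1.52-fold, and Ndufb9 rose by 0.68 on the log2 scale. Each passed over the list with any single library left out. Of 40 genes of fatty acid uptake and oxidation, 12 rose over the list alone and 0 fell (median log2 fold change 0.42, camera adjusted p = 1.55e-12, and 0.411 as the adjusted p with an estimated correlation). Among them were Ucp3, a mitochondrial uncoupling protein of muscle (52.2 ± 9.58 against 21.04 ± 7.14 CPM), Acot2, a mitochondrial acyl-CoA thioesterase (1.77-fold), Mlycd, malonyl-CoA decarboxylase (1.51-fold), and Eci2, an enoyl-CoA isomerase (1.36-fold). Of 22 genes of the tricarboxylic acid cycle, 14 rose over the list alone (median 0.42, camera adjusted p = 5.21e-12, and adjusted p = 0.411 with an estimated correlation), among them Pdhb and Pdhx of the pyruvate dehydrogenase complex (0.57 and 0.58). None of the list passed without mild cold 1, mild cold 3, room temperature 1 or room temperature 3. The 13 mitochondrially encoded genes had a median of 0.61 (camera adjusted p = 2.4e-09, and adjusted p = 0.411 with an estimated correlation), with 0 past the threshold over the list alone, where the smallest adjusted p was 0.051. Under other settings 6 passed with DESeq2 size factors or at least 1 CPM in 3 libraries, 5 with upper-quartile scaling, 8 with robust estimation or without an expression filter, 4 without mild cold 1 and 13 without room temperature 2. Their levels are uncertain, since mt-Co1 stood at 170000 CPM in mild cold while mt-Co2 stood at 180.2 CPM and mt-Co3 at 175.9 CPM, and reads of these genes can be shared with nuclear copies. The 23 genes of glycolysis and glucose uptake had a median of 0.27 (camera adjusted p = 0.00626, and adjusted p = 0.558 with an estimated correlation) with 0 members past the threshold, among them Aldoa (0.46) and Eno3 (0.58). The list call was lost without mild cold 1 (adjusted p = 0.116) or room temperature 3 (adjusted p = 0.184). In turn, 12 members passed without room temperature 2. The fatty acid count was 7 without mild cold 1, 7 without mild cold 2, 6 without mild cold 3, 20 without room temperature 2 and 6 without room temperature 3. Without the 2 deepest libraries, which leaves 2 against 2, 0 members of the oxidative phosphorylation, fatty acid and tricarboxylic acid lists passed. With library totals only, the counts were 18, 0 and 0.

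**Figure D1:**
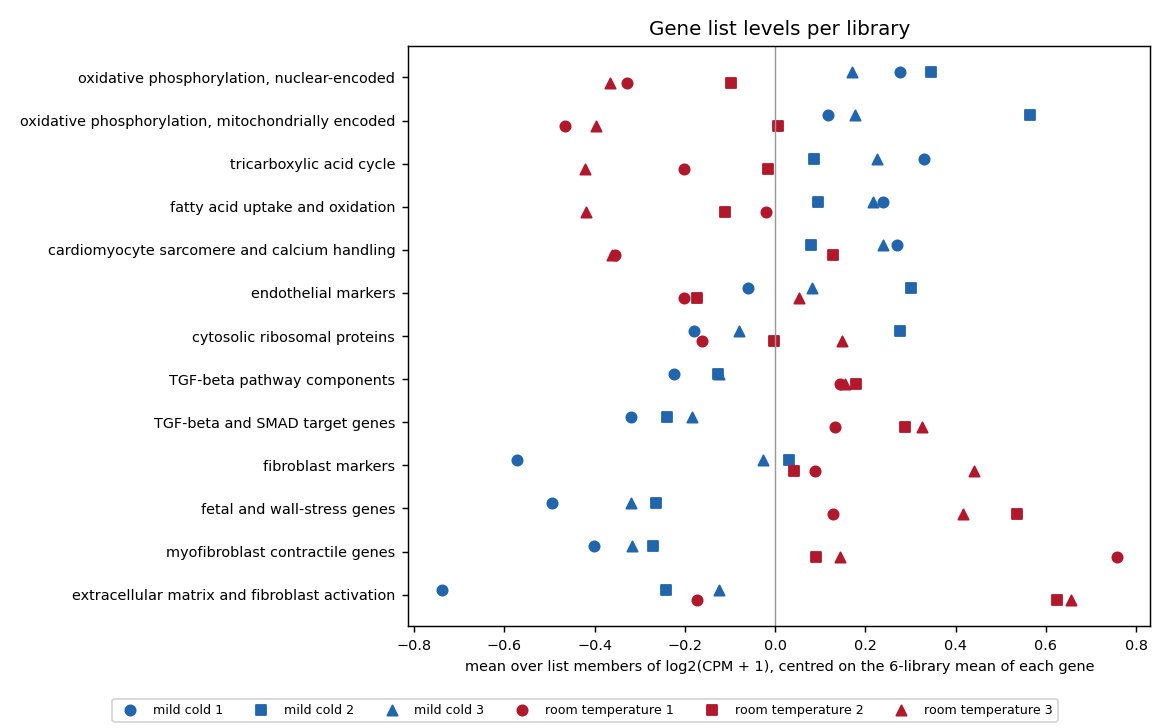
Level of 13 gene lists in each of the 6 libraries, as the mean over list members of log2(CPM + 1) after centring each gene on its mean over the libraries (no unit; blue, mild cold; red, room temperature; 1 point per library). For nuclear-encoded oxidative phosphorylation, mild cold libraries lie between 0.171 and 0.345 and room temperature libraries between -0.367 and -0.098, and for the extracellular matrix list room temperature 1 (-0.174) lies among the mild cold libraries.

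Matrix and TGF-beta genes moved downward. Fibroblast markers were lower too (median log2 fold change -0.49, camera adjusted p = 0.00123, and adjusted p = 0.495 with an estimated correlation). All 40 extracellular matrix and fibroblast activation genes had a negative fold change, and 18 fell when adjusted over the list alone, 0 over all genes (median log2 fold change -0.79, camera adjusted p = 4e-20, and adjusted p = 0.411 with an estimated correlation). Eln, the elastin gene, fell from 127 ± 34.6 to 44.5 ± 8.35 CPM, Mmp14, a membrane-bound matrix protease, from 26.4 ± 3.62 to 12.8 ± 1.03 CPM, and Col14a1, a fibril-associated collagen, from 145.4 ± 6.78 to 67.5 ± 18.1 CPM. Each of these passed over the list with any single library left out. Ccn5, a matricellular protein, fell by 1.03 on the log2 scale, but not without room temperature 3 (adjusted p = 0.0584). The fibrillar collagen genes Col1a1 (log2 fold change -0.93) and Col3a1 (-0.86) passed over the list but not without mild cold 1, mild cold 2, room temperature 2 or room temperature 3 (adjusted p up to 0.0951 and 0.124). The number of matrix genes past the threshold was 5 without mild cold 1, 6 without mild cold 2, 37 without room temperature 1, 4 without room temperature 2 and 3 without room temperature 3. Summed over the list, matrix genes stood at 6378 ± 1449 CPM in mild cold and 10460 ± 2701 CPM at room temperature (exact permutation p = 0.2), where room temperature 1 (7390 CPM) lay below mild cold 3 (7403 CPM). Of 10 myofibroblast contractile genes, 7 fell over the list alone (median -0.68, camera adjusted p = 1.38e-06, and adjusted p = 0.375 with an estimated correlation), led by Actn1, an alpha-actinin (-0.76), and Cald1, caldesmon (-0.40, lost without mild cold 3 at adjusted p = 0.0663). That count was 3 without mild cold 1, 2 without mild cold 2 and 1 without mild cold 3. The mean of the myofibroblast list was highest in room temperature 1, at 0.757 relative to the mean of all libraries. It was 0.09 and 0.144 in room temperature 2 and 3, and between -0.401 and -0.271 in mild cold. Without the 2 deepest libraries, 4 matrix and 4 myofibroblast genes fell, and with library totals only 35 matrix genes did.

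Of 26 TGF-beta and SMAD target genes, 12 fell over the list alone and 0 rose (median log2 fold change -0.61, camera adjusted p = 2.36e-11, and adjusted p = 0.0736 with an estimated correlation). Ccn2, connective tissue growth factor, fell from 598.9 ± 139 to 237.6 ± 40.2 CPM, Pmepa1, a feedback inhibitor of TGF-beta signalling, from 87.9 ± 10.7 to 43.5 ± 5.93 CPM, and Itgav, the integrin alpha-V subunit, from 60.6 ± 3.83 to 40.9 ± 2.60 CPM. The count was 6 without room temperature 3 and 20 with library totals only. Of 20 TGF-beta pathway components, 6 fell and 0 rose over the list alone (median -0.23, camera adjusted p = 1.54e-06, and adjusted p = 0.104 with an estimated correlation). They included Tgfb2 (-1.06, SE 0.11), Ltbp3, which binds latent TGF-beta (-0.77), and Skil and Ski, repressors of SMAD transcription (-0.62 and -0.46). With library totals only, 17 components fell. Tgfb2, Ltbp3 and Ski and the 3 target genes above passed over their list with any single library left out. Skil is a member of both lists and counts among the genes that fell in each, so the 2 counts are not separate. It passed over the target list with any single library left out. Both TGF-beta lists also passed fry's directional test (adjusted p = 0.00957 each), which asks whether the genes of a list move 1 way on balance and does not compare the list with other genes. The 15 SMAD ubiquitin ligases and regulators did not pass as a list (median -0.10, camera adjusted p = 0.191). Wwp2, a ubiquitin ligase that acts on SMADs, fell over that list (-0.52, list-alone adjusted p = 0.0135), but not without mild cold 3 or room temperature 2 (adjusted p up to 0.0831), while Smurf2 (-0.24), Itch (-0.20) and Usp11 (-0.42) did not pass.

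Of the genes named in the series title, Smad2 (ENSMUSG00000024563.16) stood at 27.9 ± 1.14 CPM in mild cold and 32.5 ± 2.30 CPM at room temperature, with every room temperature library above every mild cold library (log2 fold change -0.22, SE 0.09, edgeR adjusted p = 0.238, exact permutation p = 0.1). These counts measure the transcript of Smad2 and not the amount of its protein. Smad3 (-0.32, edgeR adjusted p = 0.198) and Smad4 (-0.08, 0.639) did not pass, nor did the TGF-beta ligand Tgfb1 (-0.17, 0.471) or the receptors Tgfbr1 (-0.56, 0.193) and Tgfbr2 (-0.37, 0.194). Ahr (ENSMUSG00000019256.17) stood at 11.8 ± 3.27 CPM in mild cold and 13.5 ± 3.16 CPM at room temperature (log2 fold change -0.20, SE 0.25, edgeR adjusted p = 0.69, exact permutation p = 0.6). On the log2(CPM + 1) scale the Ahr difference was -0.20, and it was 0.03 without mild cold 1. Cyp1a1, the classic AHR target gene, rose over its list from 1.26 ± 0.0966 to 3.98 ± 1.17 CPM (3.16-fold, list-alone adjusted p = 0.0114, all-gene adjusted p = 0.0878), but did not pass over its list without mild cold 1, mild cold 3, room temperature 2 or room temperature 3 (adjusted p up to 0.0718). The 21 genes of the AHR battery did not pass as a list (median 0.13, camera adjusted p = 0.116), and passed without mild cold 1 (0.0153), mild cold 2 (0.0141, with 3 members past the threshold over the list alone) or room temperature 1 (0.0451). With library totals only the median was -0.14 while camera gave the list as higher than other genes (adjusted p = 0.0382). Cyp1b1, another AHR target, was at -0.97 (SE 0.47). It stood at 9.2 CPM in mild cold 1, against 34.2 and 27.7 CPM in mild cold 2 and 3. Ahrr, the AHR repressor, was at 0.42, Tiparp at 0.16, Nqo1 at 0.20 and Arnt, the partner of AHR, at 0.04. Neither Cyp1b1 nor any of these passed. Tdo2 (3.18, SE 0.94) and Ido1 (1.36, SE 0.44), which open the indole ring of tryptophan, and Gsta4 (0.39) did not pass over the list (adjusted p = 0.0986). Tdo2 stood at 9.46, 0.483 and 11.65 CPM in mild cold 1 to 3, and Cyp1a1 at 4.62, 2.63 and 4.69 CPM. Cyp1a2, a member left out by the expression filter, had 150, 2 and 60 counts there and at most 8 in each room temperature library. Arg1 and Hamp, members of other lists picked after their values were seen, had the same order. Arg1 stood at 5.79, 0.375 and 6.25 CPM in mild cold 1 to 3, and Hamp at 1.72, 0.0536 and 1.51 CPM. The order is therefore not particular to AHR genes, and these values cannot be read as a response of AHR. Why mild cold 1 and 3 were higher than mild cold 2 was not tested. Postn (-0.37), Acta2 (-0.47) and Ppargc1a (-0.46) did not pass over all genes. Postn stood at 361.4 CPM in mild cold 1, against 669.8 and 671.4 CPM in mild cold 2 and 3. Acta2 stood at 235.5 CPM in room temperature 1, against 150.6 and 157 CPM in room temperature 2 and 3. Ppargc1a stood at 202.9, 128.8 and 89.3 CPM in room temperature 1 to 3.

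**Figure D2:**
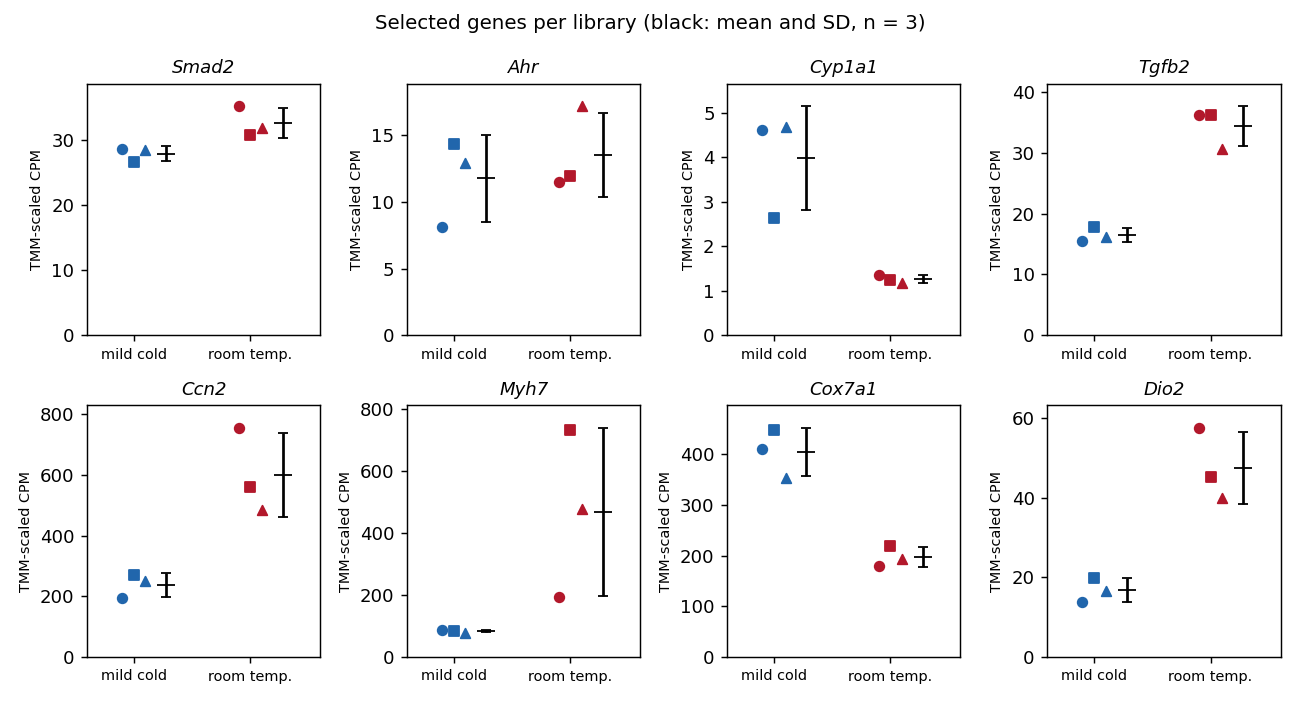
TMM-scaled CPM of 8 genes in each library (blue, mild cold; red, room temperature; black, mean and SD, n = 3 per group; each vertical axis starts at 0). Smad2 libraries lie between 26.6 and 28.6 CPM in mild cold and between 30.7 and 35.1 CPM at room temperature, while the Ahr libraries of the groups overlap.

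Fetal and wall-stress genes of the heart were lower in mild cold. Of 17 genes, 8 fell over the list alone and 0 rose (median log2 fold change -0.62, camera adjusted p = 1.65e-07, and adjusted p = 0.375 with an estimated correlation). Myh7, the beta-myosin heavy chain that returns in stressed mouse hearts, was at 82.5 ± 3.88 CPM against 467.6 ± 269.7 CPM, and Xirp1, a protein of the intercalated disc, at 110.8 ± 12.8 against 227 ± 43.6 CPM. Both passed with any single library left out. Nppb, the B-type natriuretic peptide gene (209 ± 81.9 against 490.4 ± 39.2 CPM), and Ankrd1 (-0.97) passed except without mild cold 3 (adjusted p = 0.0596 each). Nppa, the atrial natriuretic peptide gene, passed over the list (276 ± 114 against 1508 ± 1457 CPM, list-alone adjusted p = 0.0288) but not without mild cold 1 or mild cold 3 (adjusted p up to 0.0832). Its value is uncertain, since 61.5% of its exon bases are shared with another annotated gene and room temperature 1 stood at 3189 CPM (log2 fold change -2.45, and -1.28 without that library). The count was 4 without mild cold 1, 2 without mild cold 3, 5 without room temperature 2 and 5 without room temperature 3. It was 4 without the 2 deepest libraries and 13 with library totals only. Of 30 sarcomere and calcium handling genes, 2 rose and 1 fell over the list alone (median 0.40, camera adjusted p = 1.72e-08, and adjusted p = 0.438 with an estimated correlation). Tcap, telethonin of the Z-disc, rose 1.74-fold, Ckmt2, mitochondrial creatine kinase, rose 1.73-fold, but each lost its call under 4 or more of the 6 omissions (adjusted p up to 0.128 and 0.155). Myom2, an M-band protein, fell from 1010 ± 127.8 to 509.6 ± 50.7 CPM, a call lost without mild cold 3 (0.0553). Tnni3, cardiac troponin I, did not pass (0.66, adjusted p = 0.0545). The count was 0 without mild cold 3, 1 without room temperature 1, 21 without room temperature 2 and 1 without room temperature 3. Myh6, the alpha-myosin heavy chain, was at 11820 ± 2476 against 8435 ± 1878 CPM (edgeR adjusted p = 0.336). Of 21 ion channel and connexin genes, Kcnj2, an inward rectifier potassium channel, rose 1.94-fold, and Gja5, a connexin of the conduction system and vessels, fell by 1.01 on the log2 scale (median of the list 0.39, camera adjusted p = 0.0093, and adjusted p = 0.535 with an estimated correlation). Neither gene passed without any 1 of the mild cold libraries (adjusted p up to 0.102). Gja5 stood at 27.8 CPM in room temperature 1, the library that held atrial genes, against 18.7 and 15.0 CPM in room temperature 2 and 3. Its log2 fold change ranged from -1.19 to -0.72 with each library left out. In all, 7 members passed without room temperature 2 and 4 without room temperature 3. The list call was lost without mild cold 1 (adjusted p = 0.148) or room temperature 3 (0.208), and the median was 0.14 without mild cold 1 and 0.59 without room temperature 2. Kcna5 (0.43) did not pass.

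Genes of cold, stress and inflammation were mostly lower or did not pass. Of 14 cold and thermogenesis genes, 3 fell over the list alone (median log2 fold change -0.39, camera adjusted p = 0.00505, and adjusted p = 0.438 with an estimated correlation), and the list call was lost without room temperature 1 (median -0.02, adjusted p = 0.161), while the median was -0.70 without room temperature 3. Dio2, the deiodinase that activates thyroid hormone, fell from 47.5 ± 9.04 to 16.7 ± 3.001 CPM and passed with any single library left out. Rbm3, an RNA-binding protein induced by cold, fell by 0.31 on the log2 scale (list-alone adjusted p = 0.0485), a call that was lost without each of the 6 libraries in turn (adjusted p up to 0.141). Nr4a3 (-2.48) passed over the list but lost its call without any 1 of the mild cold libraries or room temperature 2, and stood at 77.7 CPM in room temperature 1 (-1.27 without that library). The count was 1 without mild cold 1, mild cold 2 or room temperature 2, and 1 with DESeq2 size factors or robust estimation. Ucp1, the uncoupling protein of brown fat, was left out by the expression filter, with 8688 counts in room temperature 1 and at most 2 in each other library. Of 24 immediate early genes, Atf3, a stress-induced transcription factor, fell from 17.7 ± 6.48 to 4.91 ± 0.749 CPM and passed with any single library left out. Nr4a2 fell by 1.23 on the log2 scale, but not without mild cold 2 or mild cold 3 (adjusted p up to 0.113). That list had a median of -0.18 (camera adjusted p = 0.0231, and adjusted p = 0.61 with an estimated correlation), and its call was lost without mild cold 2 (0.382), mild cold 3 (0.285) or room temperature 1 (0.122). Its median ranged from -0.371 without mild cold 1 to -0.005 without room temperature 1. Its count was 4 without mild cold 1, 1 without mild cold 2 and 1 without mild cold 3. Jund (-0.34) did not pass and shares 52.6% of its exon bases with another gene. Of 26 genes of the integrated stress and unfolded protein response, 4 fell and 2 rose over the list alone (median -0.33, camera adjusted p = 0.00198, and adjusted p = 0.438 with an estimated correlation), and the list call was lost without mild cold 1 (0.0766, median -0.215). Xbp1, a transcription factor of the unfolded protein response (-0.59), Edem1 (-0.52) and Asns, asparagine synthetase (-1.45, and -0.92 without room temperature 1), fell, and Herpud1 rose (0.82). None of these 4 genes passed under every omission, and the count was 0 without mild cold 3 or room temperature 1 and 3 without mild cold 1 or room temperature 3. Of 27 cytokines and chemokines, Cxcl10, an interferon-induced chemokine (-2.14), and Ccl8 (-1.19) fell and Cxcl12, a stromal chemokine (0.55), rose over the list alone, and Cxcl16 (-0.56) did not pass. The list had a median of -0.44 (camera adjusted p = 0.0449, and adjusted p = 0.451 with an estimated correlation). Its call was lost without mild cold 3 (0.0769), room temperature 2 (0.0704) or room temperature 3 (0.403), and its median was -0.28 without mild cold 2 or mild cold 3. Its member count was 0 without mild cold 1, room temperature 2 or room temperature 3, 1 without mild cold 2 or mild cold 3, and 5 without room temperature 1.

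Other biological lists did not pass with camera's preset correlation. The 30 interferon-stimulated genes had a median of -0.10 (camera adjusted p = 0.0923, led by Ifi27l2a at -1.52 and Mx1 at -1.28), and passed without mild cold 2 (2.66e-06) or room temperature 1 (0.03). The 19 circadian clock genes had a median of -0.03 (0.834), with Arntl at -1.12 and Clock at -0.34, and 4 members passed without room temperature 1. The 24 heat shock and folding genes had a median of -0.14 (0.409), with Hsp90aa1 at -0.74 and Fkbp4 at 0.43, and passed without room temperature 3 (0.001). Hspa1a (-2.22) and Hspa1b (-2.63) are near-identical copies whose counts are uncertain. The 25 NRF2 antioxidant genes had a median of 0.12 (0.195), with Sod2 at 0.56 and Gstp1 at 0.30, passed without mild cold 1 (0.046) or room temperature 1 (0.00874), and had a median of -0.15 with library totals only. The 35 cell cycle genes had a median of -0.10 (0.815), with Mki67, a proliferation marker, at -0.51 and Ccne1 at 0.67. The 75 cytosolic ribosomal protein genes had a median of 0.01 (0.512), with Rps29 at 0.44 and Rpl3 at -0.41. That list was called higher without mild cold 1 (0.00539) or room temperature 3 (0.0218) and lower without mild cold 2 (0.0289), and its genes have many processed pseudogenes, which makes their counts uncertain. The 25 angiogenesis and hypoxia genes had a median of -0.03 and a mean of 0 (0.509). Angpt2, a vessel-destabilizing ligand, fell by 0.69 on the log2 scale (list-alone adjusted p = 0.0403), but passed only without room temperature 2 among the 6 omissions, where 4 members did. Egln1 (0.64) and Egln3 (0.99), oxygen-sensing hydroxylases, did not pass (0.0669).

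Markers of cell types moved in both directions. The 15 fibroblast markers had a median of -0.49 (camera adjusted p = 0.00123, and adjusted p = 0.495 with an estimated correlation), with 0 past the threshold over the list alone, 5 without room temperature 1, 8 without an expression filter and 11 with library totals only, among them Dpt (-0.62) and Mfap4 (-1.16). The 18 endothelial markers had a median of 0.29 (camera adjusted p = 0.0021, and adjusted p = 0.438 with an estimated correlation), with 0 past the threshold over the list alone, 1 without room temperature 1, 3 without room temperature 3 and 8 without the 2 deepest libraries, among them Rgcc (0.45) and Esam (0.39). The list call was lost without mild cold 2 (0.0879). Of 7 lymphatic endothelial markers, 4 fell over the list alone (median -1.02, camera adjusted p = 0.00209, and adjusted p = 0.411 with an estimated correlation). Pdpn, podoplanin, fell from 16.0 ± 1.115 to 7.83 ± 1.51 CPM and passed with any single library left out. Reln fell by 1.02 on the log2 scale but not without mild cold 1 (adjusted p = 0.0512). The list median was -0.60 without room temperature 3. Its count was 1 without mild cold 1 and 2 without mild cold 2, mild cold 3 or room temperature 3, with robust estimation or without the 2 deepest libraries. Of 14 smooth muscle and pericyte markers, 5 rose and 4 fell (median 0.06, mean -0.14, camera adjusted p = 0.444). The pericyte genes Vtn (0.68), Kcnj8 (0.62) and Higd1b (0.57) rose and Cnn1, calponin of smooth muscle, fell (-2.39). Cnn1 stood at 34.3 CPM in room temperature 1 against 7.38 and 5.33 CPM in room temperature 2 and 3, and its log2 fold change was -1.08 without room temperature 1. None of these 4 passed without any 1 of the mild cold libraries, and with library totals only 0 rose and 5 fell. The 12 erythroid and platelet markers had a median of 0.53 (camera adjusted p = 0.000641, and adjusted p = 0.438 with an estimated correlation) with 0 past the threshold and 5 without room temperature 3. The median was 0.19 without room temperature 1 and 0.91 without room temperature 3. Hba-a2 (1.04) in that list has a near-identical copy and is uncertain.

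Among leukocyte markers, the lists of 13 T and NK cell genes (median -0.98, camera adjusted p = 0.00505), 14 B and plasma cell genes (-0.91, 0.000246) and 13 mast cell and dendritic cell genes (-1.08, 0.00459) were lower in mild cold. With an estimated correlation their adjusted p values were 0.438, 0.411 and 0.411. No member of these lists passed over its list alone, among them Cd4 (1.17 ± 0.293 against 2.31 ± 0.576 CPM). The T and NK cell call was lost without room temperature 1 (median -0.51, adjusted p = 0.105). That library had the highest mean over the T and NK cell list (0.57 relative to the mean of all libraries, against at most 0.03 in the others). It also held the thymocyte genes Rag1 (601 counts, at most 10 in each other library), Dntt (100 counts, 0 in the others) and Rag2 (32 counts, 0 in the others), and the most Cd8b1 (115 counts) and Cd3e (53 counts). Without room temperature 2, 5 T and NK cell markers passed, without mild cold 3, 5 B cell markers, and without mild cold 2, 2 mast and dendritic cell markers. The 26 macrophage and monocyte markers did not pass (median -0.24, camera adjusted p = 0.16), with Arg1, arginase, at 4.14 ± 3.27 against 0.472 ± 0.339 CPM and Gpnmb at -1.72. That list passed without room temperature 1 (0.00874) or room temperature 2 (0.0179). Arg1 stood at 5.79, 0.375 and 6.25 CPM in mild cold 1 to 3. Gpnmb stood at 36.2 CPM in room temperature 3, against 11.3 and 8.60 CPM in room temperature 1 and 2. Of 8 neutrophil markers, 3 rose over the list alone, S100a8 (2.96, SE 0.72), S100a9 (2.58, and 1.53 without mild cold 2) and Cxcr2 (2.31), at levels of 2.13 ± 1.72, 2.46 ± 2.38 and 0.71 ± 0.50 CPM in mild cold. The list did not pass (median 0.25, camera adjusted p = 0.116). The list passed without mild cold 3 (1.73e-08), room temperature 1 (0.00361) or room temperature 3 (0.00351). Its median was -0.17 without mild cold 2, and from 2.127 to 2.572 without mild cold 3 or any 1 of the room temperature libraries. Its count was 0 without mild cold 2 or any 1 of the room temperature libraries, 0 with at least 1 CPM in 3 libraries and 6 without mild cold 3.

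Genes of tissues next to the ventricle differed between single libraries. Room temperature 1 held 918.4 CPM of Myl4, the atrial myosin light chain, against 0.748 to 1.90 CPM in the other libraries, with 602.3 CPM of Myl7 and 209.1 CPM of Sln, also atrial genes. The same library was highest in fat genes, with 184.8 CPM of Ucp1, 204.3 CPM of Adipoq, the adiponectin gene, and 550.1 CPM of Cfd. Adipoq was at 0.0975, 0.0536 and 15.1 CPM in mild cold 1 to 3 and at 19.2 and 57.4 CPM in room temperature 2 and 3. Room temperature 3 was highest in the fast skeletal muscle genes Myh4 (22.3 CPM), Tnnt3 (21.8 CPM), Mylpf (18.4 CPM) and Pvalb (12.8 CPM). As lists, 17 adipocyte markers (median -3.25, camera adjusted p = 2.25e-06, and adjusted p = 0.438 with an estimated correlation), 12 epicardial and mesothelial markers (-2.76, 1.15e-05, and 0.404 likewise), 11 nerve and Schwann cell markers (-0.77, 0.00422, and 0.438 likewise) and 10 skeletal muscle markers (-3.51, 0.00238, and 0.451 likewise) were lower in mild cold. Each of these lists had 1 library that stood apart. The epicardial and nerve lists were highest in room temperature 1 (list means 1.43 and 1.01 relative to the mean of all libraries, against 0.38 and -0.11 in room temperature 2 and -0.09 and -0.02 in room temperature 3), as was the adipocyte list (2.67), and the skeletal muscle list in room temperature 3 (1.96). Without room temperature 1 the adipocyte, epicardial and nerve medians were -1.19, -1.655 and -0.34, and without room temperature 3 the skeletal muscle median was -0.685. Over the lists alone, 0 adipocyte markers fell (Lep -3.25, Fasn -3.78). Fasn stood at 1010 CPM in room temperature 1, against 86.1 and 65.9 CPM in room temperature 2 and 3. Over the other lists alone, 8 epicardial markers fell (Gpm6a -1.71, Msln -3.87) and 1 nerve marker fell (S100b -1.92). Of the skeletal muscle markers 5 fell (Actn3 -4.94, Tnnt3 -3.50, and -2.42 and -1.82 without room temperature 3). With robust estimation the epicardial count was 1 and the skeletal muscle count 0. At least 1 CPM in 3 libraries left 1 skeletal muscle marker and halved counts 0. Without mild cold 1 the last 3 counts were 0, 0 and 0, as without the 2 deepest libraries. The epicardial count was also 0 without room temperature 1 and 1 without mild cold 2 or room temperature 2. The nerve count was 0 without mild cold 2 or mild cold 3, 3 without room temperature 2 and 2 without room temperature 3. The skeletal muscle count was 0 without mild cold 2, mild cold 3 or room temperature 3 and 10 without room temperature 1 or room temperature 2, and 9 adipocyte markers passed without mild cold 3. The 11 atrial and conduction markers did not pass as a list (median -0.18, camera adjusted p = 0.191) and passed without room temperature 3 (0.00223). Of these, 4 fell over the list alone (Dkk3 -2.37, Shox2 -1.06, Nppa -2.45 and Myl4 -8.10). Without room temperature 1, Dkk3 was at -1.57 and Myl4 at -0.67. The atrial count was 0 with robust estimation, without any 1 of the mild cold libraries or without the 2 deepest libraries. The lung and thymus list was not tested as a list, since only Cd1d1 (-2.12, and -0.735 without room temperature 1) and Ager (-0.27) passed the expression filter. Of its 11 members with at least 10 counts, 10 were highest in room temperature 1. That library held 32000 counts of Scgb1a1 (681 CPM) and 5466 counts of Scgb3a2 (116 CPM), secretoglobins of the airway, where the other libraries held at most 102 and 6 counts. It held 297 counts of Sftpd and 162 of Sftpa1, surfactant proteins of the lung, against 0 in each other library. With the adipocyte, atrial and skeletal muscle genes left out, 37 lists remained to be tested and 25 passed, where the adipocyte and skeletal muscle lists had been 2 of the 27.

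**Figure D3:**
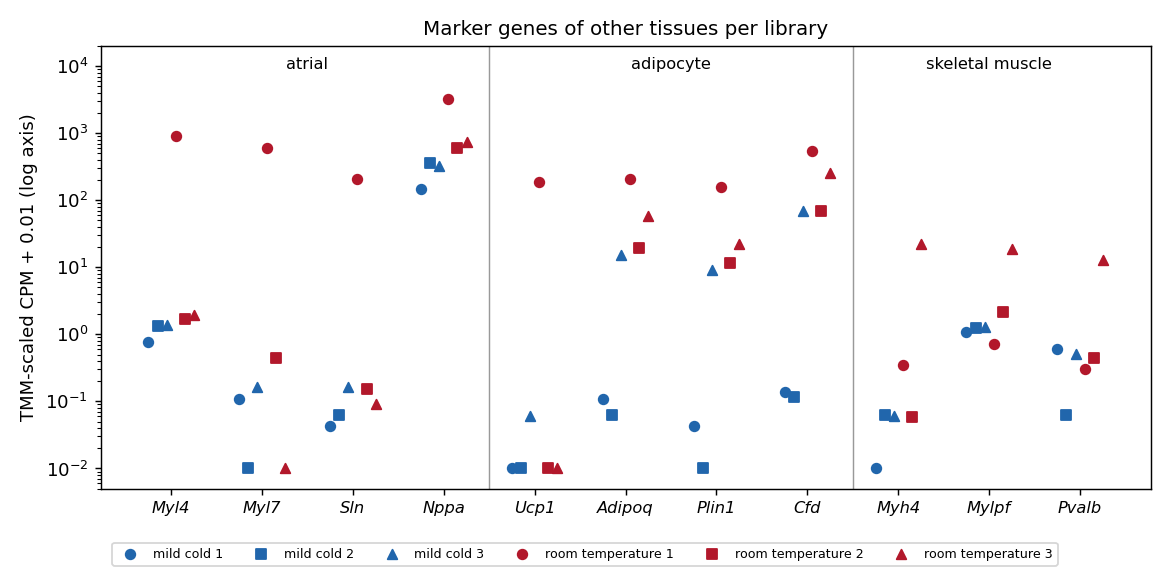
TMM-scaled CPM + 0.01, on a log axis, of 11 marker genes of atrium, fat and skeletal muscle in each of the 6 libraries (blue, mild cold; red, room temperature; 1 point per library). Room temperature 1 is the highest library for the atrial and fat genes shown, with 918.4 CPM of Myl4, and room temperature 3 for the skeletal muscle genes shown, with 22.3 CPM of Myh4.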

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

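Halved counts, leaving out the 2 deepest libraries, leaving out tissue marker genes and removing a trend on gene length and GC content were chosen after seeing the data. The count of genes past edgeR's adjusted p of 0.05 was 0, and it was 356 with library totals only, 184 without an expression filter, 1252 with the DESeq2 Wald test and 396 at a threshold of 0.1. It ranged from 0 to 2 with each library left out, where Myh7 (-2.88) and 2210407C18Rik (2.11) passed without room temperature 1. It was 0 with DESeq2 size factors, upper-quartile scaling, TMM scaling without mitochondrially encoded and haemoglobin genes, at least 1 CPM in 3 libraries, robust estimation and limma-voom. It was also 0 with a threshold of 0.01, with halved counts, without the 2 deepest libraries and without tissue marker genes. The cause of these differences was not tested.

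Of the 40 lists, 27 passed with camera's preset correlation, 0 with an estimated correlation, 2 with fry's directional test and 9 with its test for change in either direction. With each library left out 26 to 29 passed, of 40 lists tested without room temperature 1 and 41 under the other 5 omissions. It was 31 of 41 without an expression filter, 23 of 39 at 1 CPM in 3 libraries, 26 of 39 without mitochondrially encoded and haemoglobin genes, 25 of 37 without tissue marker genes, 24 of 40 with library totals only or halved counts, 29 of 40 without the 2 deepest libraries, 28 of 40 with the length and GC trend removed, and 27 of 40 with DESeq2 size factors, upper-quartile scaling or robust estimation. The lung and thymus list passed among the 41 without an expression filter or without room temperature 3. Lists that turned direction while past the threshold were cell cycle (median 0.25, adjusted p = 0.00264) and macrophage markers (0.15, 0.044), both without the 2 deepest libraries, and ribosomal proteins (-0.14 without mild cold 2, in a range of -0.14 to 0.11 with each library left out). The cause was not tested, and without the 2 deepest libraries only 4 libraries remain. With library totals only, medians of the AHR battery, NRF2, ribosomal protein, neutrophil and smooth muscle lists changed sign. In that setting the calls of the cytokine (adjusted p = 0.319), immediate early (0.0627), T and NK cell (0.115), mast and dendritic cell (0.0574), nerve (0.0627) and skeletal muscle (0.0574) lists were lost. Halved counts ended the calls of the cytokine (0.128), T and NK cell (0.349) and mast and dendritic cell (0.0555) lists, and at least 1 CPM in 3 libraries those of the cytokine (0.0704), mast and dendritic cell and skeletal muscle lists (0.208 each). Without the 2 deepest libraries the ion channel (0.938), glycolysis (0.696), cytokine (0.487), stress response (0.0582) and fibroblast (0.489) calls were lost. Of 875 list medians under these alternatives, 680 kept their sign and side of the threshold, 130 lost the threshold and 31 gained it with the same sign. Another sign was found for 34, namely the 3 lists that turned while past the threshold, 2 that gained a call as higher genes with a negative median (AHR battery and neutrophil, library totals only) and 29 that did not pass in either setting.

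Member counts adjusted over the list alone moved by over 1.5 times in these settings too. Without an expression filter, 31 matrix, 7 cold and thermogenesis, 7 T and NK cell, 10 adipocyte, 3 nerve and 9 skeletal muscle genes fell, 22 fatty acid genes rose, and 6 rose and 1 fell in each of the sarcomere and neutrophil lists. With library totals only, 7 SMAD ligase, 5 cold and thermogenesis, 6 circadian, 6 immediate early, 16 stress response, 4 angiogenesis, 6 mast and dendritic cell, 5 nerve and 8 skeletal muscle genes fell. TMM scaling without mitochondrially encoded and haemoglobin genes left 1 cold and thermogenesis gene. Without the 2 deepest libraries, 10 immediate early and 8 heat shock genes fell, 5 erythroid and platelet genes rose, and no cytokine, neutrophil or smooth muscle gene passed.

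Of 77 named genes past the threshold over their list, 24 passed under all 6 omissions and 6 under 5, and 0 changed sign while past it. Differences on log2(CPM + 1) with each library left out or another pseudocount or scaling ranged from -0.46 to -0.16 for Smad2, from -0.43 to 0.03 for Ahr and from -0.96 to -0.50 for the matrix sum. With each library left out alone Ahr ranged from -0.35 to 0.03, where 0.03 came without mild cold 1 and the cause was not tested.

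The replicate numbers gave no sign of pairing. Deviations of libraries with the same number correlated at 0.097, -0.173 and -0.087, and not every library correlated best with its own number. These values cannot show that no day or batch was shared, since deviations from the mean of only 3 libraries must balance out within each group. With the replicate number as a block, 1 gene passed, 30 lists passed with the preset correlation and 0 with an estimated correlation. Over the lists alone it gave 9 mitochondrially encoded genes rising, and 35 matrix, 8 fibroblast, 4 B and plasma cell, 3 myofibroblast, 3 heat shock, 2 nerve, 2 skeletal muscle, 1 epicardial and 0 atrial genes falling, with 3 rising and 1 falling smooth muscle genes and 1 falling sarcomere gene. Depth limits what can be seen for genes near 1 CPM, such as Cd4. With each gene drawn at its fitted dispersion, the simulated test recovered 9 of 50 genes changed 1.5-fold, which need not hold for the real data.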

Other observations

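All tests in this part were chosen after the results were seen, except the counts of splits and the tests on atrial and fat genes outside the fixed lists. Gene families outside the fixed lists were gathered by symbol, 22 in all, and 9 passed camera's test (5 higher and 4 lower in mild cold) but 0 with an estimated correlation. Mitochondrial ribosomal proteins, which translate the mitochondrial genome, were higher, with 59 of 77 rising when adjusted over the family alone (median log2 fold change 0.41, camera adjusted p = 7.83e-30, and adjusted p = 0.267 with an estimated correlation), for example Mrpl14 (0.76) and Mrps24 (0.54). Assembly factors of the respiratory complexes (median 0.38, 11 of 23 rising, Uqcc2 0.66), coenzyme Q synthesis genes (0.40, 7 of 11, Coq10a 0.68) and mitochondrial import genes (0.29, 4 of 22, Timm23 0.47) were higher too (camera adjusted p = 3e-08, 2.4e-05 and 3.26e-06, and 0.267, 0.267 and 0.277 as the adjusted p with an estimated correlation). The Slc25 carriers did not pass (median 0.07, adjusted p = 0.186, 0 members past the threshold), but passed without room temperature 1 (0.0416), and 7 members rose and 1 fell without room temperature 2. Their median was -0.19 with library totals only. Without the 2 deepest libraries 0 members of these 4 families passed, and with library totals only their medians were 0.16, 0.13, 0.15 and 0.04 with 0 members past the threshold. The ribosomal protein count was 35 without mild cold 1 and 31 without room temperature 3, the assembly factor count 2 without mild cold 1 or mild cold 3, 7 without mild cold 2, 6 without room temperature 1, 3 without room temperature 3 and 7 with upper-quartile scaling, the coenzyme Q count 0 without mild cold 1 or room temperature 3, and the import count 12 without room temperature 2, 1 without mild cold 2 and 0 under each other omission. Proteasome subunits had a median of 0.15 (camera adjusted p = 0.000104, and adjusted p = 0.483 with an estimated correlation) with 0 members past the threshold and 6 rising without room temperature 2. With library totals only the median was -0.10 and the call was lost (adjusted p = 0.124).

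On the side of the matrix, all 25 collagen genes outside the fixed list had negative fold changes and 7 fell over the family alone (median -1.07, camera adjusted p = 7.58e-10, and adjusted p = 0.267 with an estimated correlation). Among those 7 were Col18a1 (-1.03) and Col27a1 (-1.07), and the cartilage collagens Col2a1 (-6.06, SE 1.24), Col9a2 (-2.58, SE 0.595) and Col11a1 (-1.94, SE 0.468). The family median was -0.59 without room temperature 1, the library that also held airway genes. The count was 4 without mild cold 1, 3 without the 2 deepest libraries and 13 with library totals only. Of 23 genes gathered by integrin symbols, 12 fell and 1 rose (median -0.62, camera adjusted p = 0.000159, and adjusted p = 0.267 with an estimated correlation). Among those that fell were Itgb3 (-0.62) and the leukocyte integrin Itgal (-1.31). The gene that rose was Itgb1bp2 (0.59), which encodes an integrin-binding protein and is not an integrin. In this family 0 members passed without mild cold 1, mild cold 3, room temperature 3 or the 2 deepest libraries. In turn, 5 fell without mild cold 2, and 7 fell and 2 rose without room temperature 2. Of 17 Wnt ligands and Frizzled receptors, 3 fell (median -0.35, camera adjusted p = 0.0232, and adjusted p = 0.375 with an estimated correlation), among them Fzd7 (-0.67) and Fzd1 (-0.70), with 0 members past the threshold without mild cold 1, any 1 of the room temperature libraries or the 2 deepest libraries. The median was -0.56 without room temperature 2, and the family call was lost without room temperature 1 (0.0977) or the 2 deepest libraries (0.0776), and with library totals only (0.0827). The ADAM and ADAMTS proteases had a median of -0.45 (camera adjusted p = 0.0232, and adjusted p = 0.267 with an estimated correlation), and -0.23 without room temperature 1. Of 29 members, 3 fell (Adamts1 -0.51, Adam19 -0.75, Adamts2 -0.75) and 2 rose (Adam22 0.55, Adamts7 0.91), with at most 1 rising and 2 falling under any omission. The family call was lost without mild cold 2 (0.163), room temperature 3 (0.0731) or the 2 deepest libraries (0.0693), and with library totals only (0.0827), where 7 members fell and 0 rose.

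The 10 splits of the 6 libraries into 3 against 3 are too few for a share under 0.05. The real split gave 0 genes past edgeR's adjusted p of 0.05, and so did all 10 splits. It gave 3295 genes at an unadjusted p under 0.05, where the highest other split gave 1557, so 1 of 10 splits reached the real value. It gave 27 lists past camera's threshold, where the highest other split gave 22 and the lowest 16, so 1 of 10 reached 27 and camera with its preset correlation called many lists under every grouping of these libraries.

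Oxidative phosphorylation genes were higher and matrix genes lower in mild cold with camera's preset correlation, which the p-values here use, but not with an estimated correlation (adjusted p = 0.375 and 0.411). For oxidative phosphorylation, other tissue in room temperature 1 is argued against as the whole source, since without that library the median was 0.49 (camera adjusted p = 4.8e-39). For the matrix list, room temperature 1 (list mean -0.174) already lay below room temperature 2 and 3 (0.624 and 0.656). The matrix difference did not rest on that library, and leaving it out could only widen the difference (median -1.01, camera adjusted p = 5.66e-51), so this was no test. Gene length and GC content are argued against too, since with that trend removed the medians were 0.54 (7.29e-33) and -0.67 (9.42e-13). There was little such trend to remove, with a Spearman rho across genes of -0.131 with length and 0 with GC content. A higher share of cardiomyocytes with an equal fall of all other cells is argued against by the endothelial median, which lay 0.78 above the fibroblast median. That rests on a single list, whose call was lost without mild cold 2. Fibroblast, lymphatic, T and NK cell, B cell and mast cell lists were lower and sarcomere genes higher (median 0.40), while erythroid and platelet markers were higher too (0.53). Another change in the mix of cells therefore stays open. A lower share of fibroblasts may underlie the matrix part and stays open: matrix relative to fibroblast markers was -0.17, -0.27 and -0.10 in mild cold 1 to 3 and -0.26, 0.58 and 0.22 in room temperature 1 to 3, so that the lowest room temperature library lay below the highest mild cold library (gap -0.16), and an effect of temperature on the heart, or on how much of each heart was scar, was not tested.

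Room temperature 1 held atrial and fat genes, and airway and thymus genes as well (Scgb1a1 at 681 CPM and Rag1 at 12.8 CPM). Atrial and fat tissue in that sample is a candidate explanation: 9 of 10 atrial genes outside the fixed list were highest there, with a median of 2.04 times the highest other library (Mybphl, Sbk3 and Fgf12 among the strongest), and so were 11 of 11 fat genes, at 3.72 times (Car3, Elovl6 and Acvr1c among them). Housing temperature alone is argued against as the source of most of this excess, since room temperature 2 and 3 held little of it. The pattern was picked because room temperature 1 stood out, which makes small shares likely, so a smaller effect of housing cannot be excluded. The median share in room temperature 2 and 3 was 0.00047 over 12 atrial list members (upper quartile 0.158). Over 18 fat list members it was 0.0495 (upper quartile 0.161), where a shared source needs over 0.5. The shares above 0.5 were Lep (0.917) and Bmp10 (3.57). The other 3 detected atrial members (Kcnk3, Tbx3 and Hcn4) had no excess in room temperature 1 to share. These bounds and members were settled after the values were seen: a first bound of 0.1 was missed by both upper quartiles, the atrial median was first taken over the 10 members highest in room temperature 1 (0.00019) and then over all 15 (0.000721, upper quartile 0.316), and in an earlier count 11 of 28 tested members had all room temperature libraries above all mild cold libraries. A whole heart, as labelled, has atria, so whether atria were left out of the other 5 samples or added to this one, whether the rest was dissected with the heart or came from RNA of another sample, and what smaller differences in fat genes between the other libraries come from were not tested.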
